A study of Sinorhizobium meliloti RU11/001 with 6 samples.

How the data were processed

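RNA was sequenced from 6 samples of Sinorhizobium meliloti RU11/001, 3 libraries of the wild type and 3 of the strain lacking ldtR. Per the labels' protocols, RNA was isolated with a column kit that stabilises bacterial RNA, 1.25 µg of each sample was depleted of ribosomal RNA, and libraries were made with a strand-preserving Illumina kit. Groups and replicate numbers were taken from the sample titles.

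Each library came with 1 table of 7657 coding sequences, which gave locus tag, product and replicon. Per the file headers the authors deposited raw read counts, which are estimated counts here because 36.91% to 38.24% of the values per library were not whole. Per the file headers the tables were made from trimmed reads; the aligner, the counting program, the genome build and whether counting used the strand are not given in the sources used here. The RPKM values (reads per kilobase of gene, scaled to library size), deposited by the authors beside the counts, served only to work out coding lengths. The authors' deposited table of the strain comparison, made with DESeq2 per the labels, held a log2 ratio and an adjusted p-value per gene, and the p-value was missing for 810 genes. The sign of its log2 ratio was read from the deleted gene, which was lower in the mutant libraries. In 5789 genes at least 1 library had a count that was not whole, as when a read is divided between places, so values for near-identical or overlapping genes are uncertain. The same holds for genes opposite another gene on the other strand.

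Counts were rounded to whole numbers. Library totals were 9919500 to 11674289 counts, and the most abundant gene held 4.11% to 4.67% of each. Genes were kept with edgeR's filterByExpr (smallest count 10 in the default setting, smallest total 15), which left 7493. The test was edgeR's quasi-likelihood F-test with robust fitting and trimmed-mean (TMM) factors, the mutant against the wild type with no covariate, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and a second count required a fitted change of at least 2-fold. Log2 fold changes are mutant over wild type, each with its standard error (SE). Levels are CPM (counts scaled to a common library size) on the TMM-scaled library sizes, given as mean ± SD with n = 3. The biological coefficient of variation was 26.5%. Pairs of libraries were compared by a chi-square over genes, and the lowest value per degree of freedom was 20.82, so no pair was treated as 1 library.

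Gene lists (26, by symbol or product) were fixed before the data were examined, and 23 had at least 3 tested members. They were tested with camera from limma on voom log2 CPM with the preset correlation of 0.01 between genes, beside an estimated correlation and fry. Calls per replicon were compared by Fisher's exact test, two-sided, for the chromosome, pSymA and pSymB, with higher and lower calls apart. The genes named are, first, ldtR, its annotated neighbours, ldtP, motA and motS. Next come 2 to 4 members of the flagellar regulator, motor and flagellin lists and of every called list, or list with at least 3 called members, by size of change. Last come the 10 largest rises and the 10 largest falls among called genes whose 3 values in a group all lay above those of the other, at a mean of at least 20 counts. Other genes and runs named for their values fall outside these rules and were named after the values were seen. This holds for visR, mcpZ, SMRU11_27785 and the run SMRU11_13190 to SMRU11_13205, where it is not repeated. Few genes carry a symbol in these tables (97), and ldtR and ldtP do not. The deleted gene was taken to be SMRU11_37885, a regulator gene of the MarR family beside a murein L,D-transpeptidase gene, SMRU11_37880, taken to be ldtP; motS is not analysed here. A table of reference genes from another species shared 0 locus tags with these tables and was not used, and no genome coordinates are used here.

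Alternatives fixed before the data were examined were DESeq2, other scaling factors, other filters, leaving out the most abundant genes, the likelihood ratio test, a test against a 2-fold bound, the replicate number as a block and leaving out each library. A fit on 4 libraries and a fit with the share of counts on the plasmid pSmeRU11c as a covariate were added after the data were seen. On simulated counts for this comparison with 200 changed genes, in a fit of 7472 genes, edgeR recovered 10% of the genes changed 1.5-fold, 54% at 2-fold, 92% at 4-fold and 100% at 8-fold, and called 7 of 7252 unchanged genes. DESeq2, on 7493 genes, recovered 14%, 60%, 96% and 100% at these sizes and called 25 of 7273 unchanged genes. Each simulated gene was drawn independently, without differences that many genes share between libraries, so these rates may not hold for the real libraries. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.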

Results

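Sinorhizobium meliloti is a soil bacterium that swims with flagella and forms nitrogen-fixing nodules on legume roots. The study asked how the loss of LdtR, a transcriptional regulator, changes gene expression under conditions that favour swimming, since the strain without it moves poorly. RNA was sequenced from the wild type RU11/001 and from the strain lacking ldtR (ΔldtR), with 3 libraries each. Cultures were grown for 17 hours at 30 °C in overlay plates of Bromfield medium and taken at an optical density of 0.20 to 0.25. The wild-type libraries held 11181761, 11511508 and 10433960 counts and the ΔldtR libraries 11072019, 9919500 and 11674289, spread over 7657 coding sequences. The labels do not say that the libraries of a strain came from separate cultures, so the p-values measure only the spread between these samples, which may be technical or lie in the cultures.

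The deleted gene was checked first. SMRU11_37885, the MarR family regulator gene taken to be ldtR, fell from 244 ± 23.3 CPM in the wild type to 12.7 ± 1.22 CPM in ΔldtR (SD, n = 3), which was 19.1-fold lower (log2 fold change −4.26, SE 0.13, edgeR adjusted p = 4.4e-06). Each ΔldtR library lay below each wild-type library, so the gene matched the strain given for all 6. The mutant libraries still held 417 counts in this gene, 5.19% of the wild-type level (exact 95% interval 4.70% to 5.71%, counting error only). The gene on one side, SMRU11_37880, encodes a murein L,D-transpeptidase, an enzyme type that cross-links the cell wall, and was taken to be ldtP. It had 312 ± 13.2 CPM in the wild type and 348 ± 22.7 CPM in ΔldtR (log2 fold change 0.16, SE 0.10, adjusted p = 0.544). The hypothetical gene on the other side, SMRU11_37890, had a log2 fold change of −0.06 (SE 0.14, adjusted p = 0.908). For motA, which encodes a subunit of the stator that drives flagellar rotation and is named in the study's title, the levels were 349 ± 74.1 and 284 ± 22.2 CPM (log2 fold change −0.30, SE 0.16, adjusted p = 0.497).

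With all 6 libraries the largest called changes in ΔldtR were falls, led by a small set of genes that almost lost their transcripts. Transglutaminase gene SMRU11_36780 fell from 40.4 ± 3.08 to 0.833 ± 0.297 CPM, 47.2-fold lower (log2 fold change −5.56, SE 0.22, adjusted p = 2.29e-05). A sigma-54-dependent regulator gene of the Fis family, SMRU11_27695, fell from 171 ± 10.02 to 11.6 ± 1.03 CPM, 14.7-fold lower (adjusted p = 4.4e-06). SMRU11_32230, whose product carries a GGDEF domain, the domain that makes the second messenger cyclic di-GMP, was 9.42-fold lower (adjusted p = 6.45e-04). The other 6 of the 10 largest falls were hypothetical genes. SMRU11_27440 was 22.9-fold lower, the neighbours SMRU11_17900 and SMRU11_17905 on pSymB were 21.8-fold and 8.74-fold lower, SMRU11_32755 was 13.2-fold lower, and SMRU11_20280 and SMRU11_33790 were 7.03-fold and 7.02-fold lower. Of the 10 largest falls, ldtR included, the call of SMRU11_20280 was lost without wild type 1 (adjusted p = 0.056), and the others were called without any 1 of the 6 libraries.

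The called rises were smaller. The 10 largest held pSymA genes of an ABC transporter, a type of uptake or export pump. Its substrate-binding protein gene SMRU11_09835 rose from 57.5 ± 8.8 to 187 ± 39.6 CPM, 3.26-fold (log2 fold change 1.70, SE 0.19, adjusted p = 0.0107), and its ATP-binding protein gene SMRU11_09830 rose 2.90-fold. Nearby hypothetical gene SMRU11_09810 rose 2.96-fold. Also on pSymA, the neighbouring genes of a D-amino acid aminotransferase, SMRU11_09475, and an aminopeptidase, SMRU11_09480, rose 2.73-fold and 2.26-fold, and the MFS transporter gene SMRU11_04175 rose 2.08-fold. On the chromosome, catalase A (SMRU11_20750), which breaks down hydrogen peroxide, rose 2.14-fold (adjusted p = 0.024), DUF2312 gene SMRU11_21960 2.24-fold and membrane protein gene SMRU11_22215 2.18-fold. Hypothetical gene SMRU11_13520 of pSymB rose 2.46-fold (adjusted p = 0.00148). Of these 10 rises SMRU11_09480 and SMRU11_13520 were called whichever library was left out. Calls were lost for 8 without wild type 1 (highest adjusted p = 0.248), 8 without wild type 2 (0.16), 4 without wild type 3 (0.112), 4 without ΔldtR 2 (0.0985) and 7 without ΔldtR 3 (0.201).

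**Figure D1:**
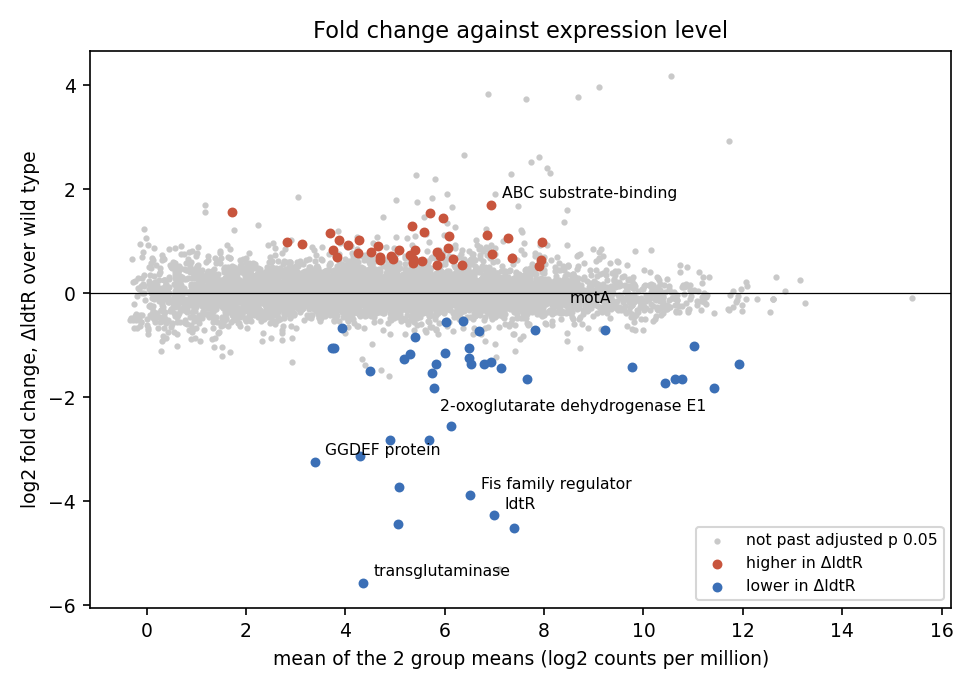
Log2 fold change of each tested gene, ΔldtR over wild type, against the mean of the 2 group means in log2 CPM; each point is 1 gene, blue for the 41 genes called lower, red for the 41 called higher and grey for the others. The lowest point is the transglutaminase gene at −5.56, ldtR lies at −4.26 and motA at −0.30, and the highest red point is the ABC substrate-binding gene at 1.70.

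Of 7493 genes tested, 41 were higher and 41 lower in ΔldtR, and at least 2-fold changes were called for 12 higher and 34 lower genes. Falls of at least 4-fold were called for 11 genes, and the largest called rise was 3.26-fold. Hypothetical proteins made up 29 of the 82. All 82 had 3 values in one strain above the 3 of the other, as did 1494 of the tested genes (19.9%, with 10% given by chance). At an unadjusted p under 0.05 there were 966 genes, against 375 by chance. Counts that were not whole occurred in 57 of the 82, whose values carry the uncertainty of divided reads. DESeq2 called 139 higher and 85 lower. The count of 82 and its balance moved with the libraries, to 2 higher and 14 lower without wild type 1, 2 and 18 without wild type 2, 15 and 25 without wild type 3, 299 and 132 without ΔldtR 1, 10 and 30 without ΔldtR 2 and 3 and 16 without ΔldtR 3. Among changes of at least 2-fold the balance turned to 60 higher and 37 lower without ΔldtR 1, whereas lower calls outnumbered higher ones in each of the other 5 fits.

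Called genes often lay side by side, in 15 runs that held 44 of the 82, where 1000 random draws of as many genes gave a median of 0 and at most 8. The draws ignore that neighbours may be transcribed together or share divided reads, so they do not test an effect of LdtR. Without wild type 1 every run lost calls except SMRU11_17900 to SMRU11_17905 and SMRU11_33785 to SMRU11_33790. The longest run, named after its values were seen, was SMRU11_26295 to SMRU11_26330 on the chromosome, 8 genes with a median log2 fold change of −1.54. Its malate dehydrogenase, 2 succinyl-CoA ligase subunits, 2-oxoglutarate dehydrogenase E1 subunit and dihydrolipoamide succinyltransferase are enzymes of the citric acid cycle. Malate dehydrogenase SMRU11_26295 fell from 2407 ± 431 to 764 ± 132 CPM (log2 fold change −1.66, SE 0.19, adjusted p = 0.0137). The E1 subunit, SMRU11_26310, fell from 4292 ± 889 to 1209 ± 350 CPM (log2 fold change −1.83, SE 0.26, adjusted p = 0.0282). A run of 4 genes on pSymB, SMRU11_13190 to SMRU11_13205, with glycosyl transferase and glycoside hydrolase genes, had a median of −1.11, with 1 call left without wild type 1, 2 without wild type 2, wild type 3 or ΔldtR 2, and 3 without ΔldtR 3. In the 8-gene run 1 call was left without wild type 1, 0 without wild type 2, 3 without wild type 3 and 0 without ΔldtR 3, with a median of −1.41 to −1.72 over the 6 fits.

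Flagellar genes were slightly lower in ΔldtR as lists, while with all 6 libraries each gene by itself missed the test over all genes. The lists of basal body, hook and export genes (23 members, median log2 fold change −0.32, camera adjusted p = 1.7e-09), motor genes (9, −0.30, 4.86e-04) and flagellar regulators (5, −0.36, 0.00124) were called as lower. Without wild type 1 these medians shrank to −0.24, −0.22 and −0.22. With an estimated correlation and all 6 libraries the adjusted p was 0.644 for each of these 3 lists, so these calls rest on the preset correlation. By fry the adjusted p was 0.206, 0.241 and 0.148. The 4 flagellins, which form the filament, had a median of −0.21 and were not called (adjusted p = 0.131). Of the 41 genes in the 4 lists, 39 had a negative log2 fold change (with library totals as the scaling, 22 rather than all 23 of the basal body list). In 30 all ΔldtR values lay below all wild-type values, where chance gives 5% per gene and all tested genes gave 716 of 7493. The genes move together (estimated correlation 0.52 to 0.641 in the 3 called lists), so 1 order of the libraries settles many of them at once.

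Over all genes edgeR called 0 of these 41, against 27 lower at an unadjusted p under 0.05 and 2 called lower by DESeq2. Without ΔldtR 1 edgeR called 1 motor gene lower. Adjusted over the list alone, 2 motor genes and 3 regulators were lower, and 0 basal body genes and 0 flagellins. Among motor genes, motB, which encodes the other stator subunit, went from 343 ± 51.6 to 225 ± 11.1 CPM (log2 fold change −0.61, SE 0.13, adjusted p = 0.0932, and 0.016 over the list alone). A second MotA-annotated gene, SMRU11_27785, had 0.07. Of the same list motC had −0.42, fliN of the rotor switch −0.40 and fliK −0.36. The regulators at the top of the flagellar cascade, visN and visR, had −0.44 and −0.26, and rem, which acts below them, had −0.37. In the basal body and export list fliE and fliI had −0.48 each, fliQ −0.43 and flhA −0.42. The most abundant flagellin gene, flaA, stood at 10431 ± 1554 CPM in the wild type and 9171 ± 627 CPM in ΔldtR (−0.19), and flaB, flaC and flaD had −0.34, −0.24 and 0.03. Relative to the mean of the 6 libraries on the log2 scale, the median over the 41 genes was 0.33, 0.13 and −0.03 in wild type 1, 2 and 3, and −0.19, −0.13 and −0.14 in the 3 ΔldtR libraries.

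**Figure D2:**
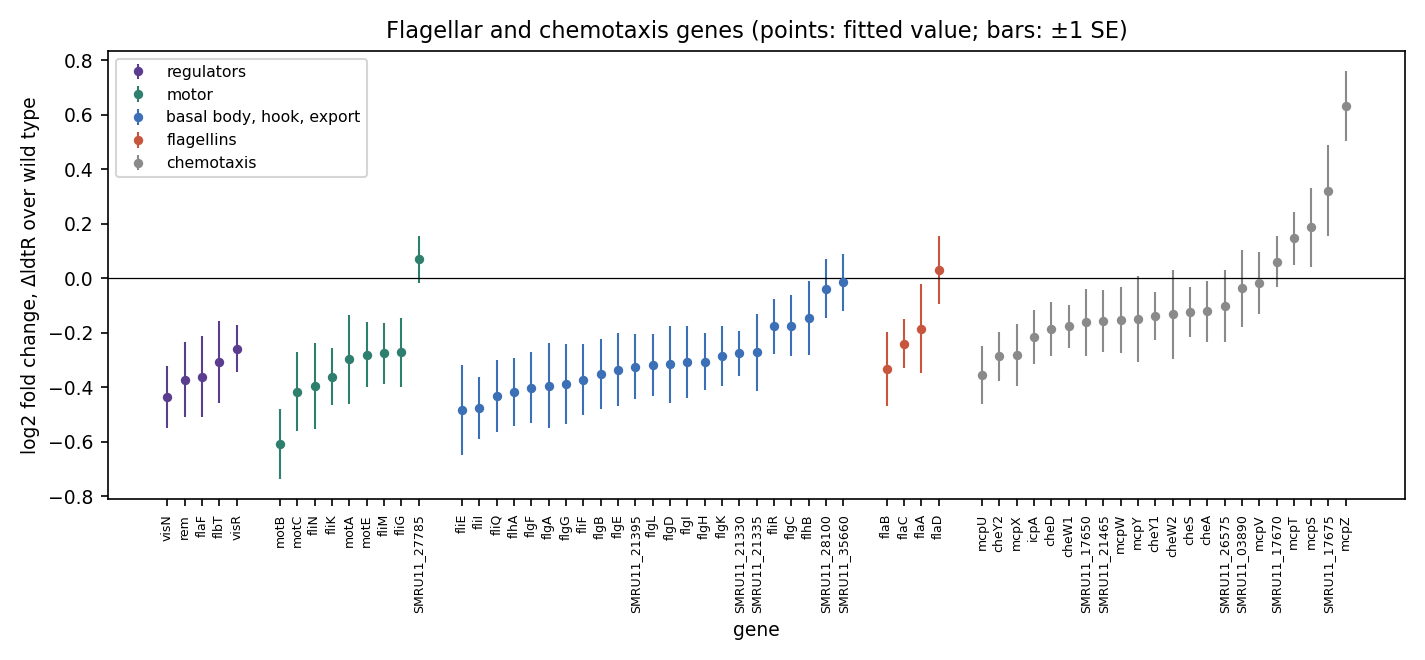
Log2 fold change of each flagellar and chemotaxis gene, ΔldtR over wild type, in order of size within each of 5 lists; points are fitted values from 3 libraries per strain and bars are ±1 SE. Of the 41 flagellar genes 39 lie below 0, with motB lowest at −0.61, and among the chemotaxis genes mcpZ stands out at 0.63.

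Chemotaxis genes, which steer swimming, were not called as a list (22 members, median log2 fold change −0.14, adjusted p = 0.0732). The member with the largest change was mcpZ, a chemoreceptor gene, at 220 ± 34.8 and 341 ± 13.4 CPM (log2 fold change 0.63, SE 0.13, adjusted p = 0.0828). It was higher when adjusted over the list alone (0.0324), as 1 of 22. With all 6 libraries edgeR called 0 of the 22 over all genes, against 1 higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower. Without ΔldtR 1, in the fit on 4 libraries and with the pSmeRU11c covariate, edgeR called 1 of them higher. The list was called as lower without wild type 2 (adjusted p = 0.00956), ΔldtR 2 (0.0373) or ΔldtR 3 (0.0258) and with the stricter filter (0.0306), while it had 0.43 without wild type 3 and 0.316 without ΔldtR 1. With an estimated correlation and all 6 libraries its adjusted p was 0.746.

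Ribosomal protein genes were called as lower as a list (57 members, median log2 fold change −0.20, camera adjusted p = 2.93e-04). With an estimated correlation the adjusted p was 0.746, and by fry it was 0.552. All 57 had a negative log2 fold change, or 56 with library totals as the scaling, and 0 had the strains apart. The largest were L23 (SMRU11_37065) at −0.49, L29 (SMRU11_37035) at −0.47 and L34 (SMRU11_22655) at −0.46. edgeR called 0 of them over all genes and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. The list median relative to the mean of the libraries was 0.62 in ΔldtR 1, −0.80 in ΔldtR 2 and −0.26 in ΔldtR 3, against 0.00 to 0.23 in the wild type. Without ΔldtR 2 the median was 0.05 and the list was not called (adjusted p = 0.702), and without ΔldtR 1 the median was −0.70 with 11 genes called lower (adjusted p of the list 1.61e-18).

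The other 17 lists tested, which covered the cell wall, the cell surface, stress responses, nutrient uptake, symbiosis and housekeeping genes, were not called (adjusted p 0.0828 to 0.999). With all 6 libraries they held 3 called genes. These were catalase A, the GGDEF gene SMRU11_32230 and a Flp pilin gene, SMRU11_24385, which fell by 0.70 on the log2 scale (adjusted p = 0.0324) and was not called without either wild type 1, 2 or 3 or ΔldtR 2 or 3 (highest adjusted p = 0.219). Among the 12 L,D-transpeptidase genes and the 24 peptidoglycan synthesis genes edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Without ΔldtR 1, and also in the fit on wild type 1 and 2 and ΔldtR 2 and 3, edgeR called 1 L,D-transpeptidase gene higher and 1 lower and 1 peptidoglycan synthesis gene higher. With all 6 libraries their median log2 fold changes were −0.15 and 0.03. Heat shock and chaperone genes (34) had a median of 0.12. They were higher by fry, which asks whether a list's genes move one way (adjusted p = 0.0266), and not by camera (0.0828). Lists of this group were called when 1 library was left out, heat shock (adjusted p = 0.0409) and iron uptake (0.0272) as higher without wild type 2, and osmoprotectants (0.0305) as higher and the respiratory chain (0.00446) as lower without ΔldtR 1. With an estimated correlation and all 6 libraries the adjusted p was 0.644 for heat shock and 0.746 for each of the other 3. In all, 7 lists were called without wild type 2 and 6 without ΔldtR 1 in place of 4. Single calls in the 17 lists moved as well. Without ΔldtR 1 there were 2 oxidative stress genes higher, 2 cyclic di-GMP genes lower, and 1 Flp pilus or type IV secretion gene higher and 2 lower. The respiratory chain, iron uptake, nitrogen assimilation, nodulation and osmoprotectant lists then held 1 call each. Without wild type 1 only the cyclic di-GMP list held a call, 1 lower.

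The genome of this strain is divided into a chromosome, the megaplasmids pSymA and pSymB and smaller plasmids. Lower calls were 28 of 3786 genes on the chromosome, 13 of 1592 on pSymB and 0 of 1662 on pSymA, against 41 of 5831 off pSymA (Fisher's exact test, two-sided, adjusted p = 4.49e-04 over 6 tests). On pSymA 37 genes were lower at an unadjusted p under 0.05, and DESeq2 called 2. Higher calls were 23 on the chromosome, 10 on pSymA and 5 on pSymB, and none of these 3 shares passed the test (adjusted p 0.274 to 0.708). The result for pSymA was lost without wild type 1 (0.172), wild type 2 (0.117) or ΔldtR 3 (0.187), and the test treats genes as independent although called genes lay in runs. It also takes no account of level or spread. Of the pSymA genes 321 of 1662 were higher in both wild type 3 and ΔldtR 1 than in each other library, against 1013 of all 7493. The lack of lower calls thus does not show that pSymA genes were unaffected.

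A pair of libraries, wild type 3 and ΔldtR 1, stood apart from the other 4. The first principal component of log2 CPM held 59.9% of the variance and placed them at 32.0 and 32.4, with wild type 1 and 2 at −0.68 and −5.42 and ΔldtR 2 and 3 at −29.8 and −28.5. Counts on plasmid pSmeRU11c made up 5.07% and 5.09% of these libraries and 1.10% to 1.54% of the others, and pSymA held 11.52% and 11.74% against 6.75% to 8.13%. In all, 1013 genes (13.5%) were higher in both than in each of the 4 others. Chance gives 6.67% for 2 libraries fixed beforehand, but this pair was picked for standing apart, so the share describes it and does not test it. The 1013 genes included, named after their values were seen, the cbb3 oxidase gene SMRU11_04710, part of a respiratory enzyme with high affinity for oxygen, at 4012 and 3974 CPM against 310 to 917. Arginine deiminase gene SMRU11_06385 stood at 284 and 261 CPM against 15.98 to 30.2. On the other 4 libraries alone, a choice made after seeing the data, edgeR called 432 genes higher and 246 lower, all 82 among them, and at least 2-fold changes for 83 higher and 65 lower genes. In that fit the median over the 41 flagellar genes was −0.37, with 4 basal body genes, 3 motor genes and 1 regulator called lower, and the ribosomal protein genes had a median of −0.59 with 13 called lower. Among these 4 libraries the strains still differed along the first component, where wild type 1 and 2 lay between the pair and ΔldtR 2 and 3. The fit therefore cannot separate the strain from that axis.

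**Figure D3:**
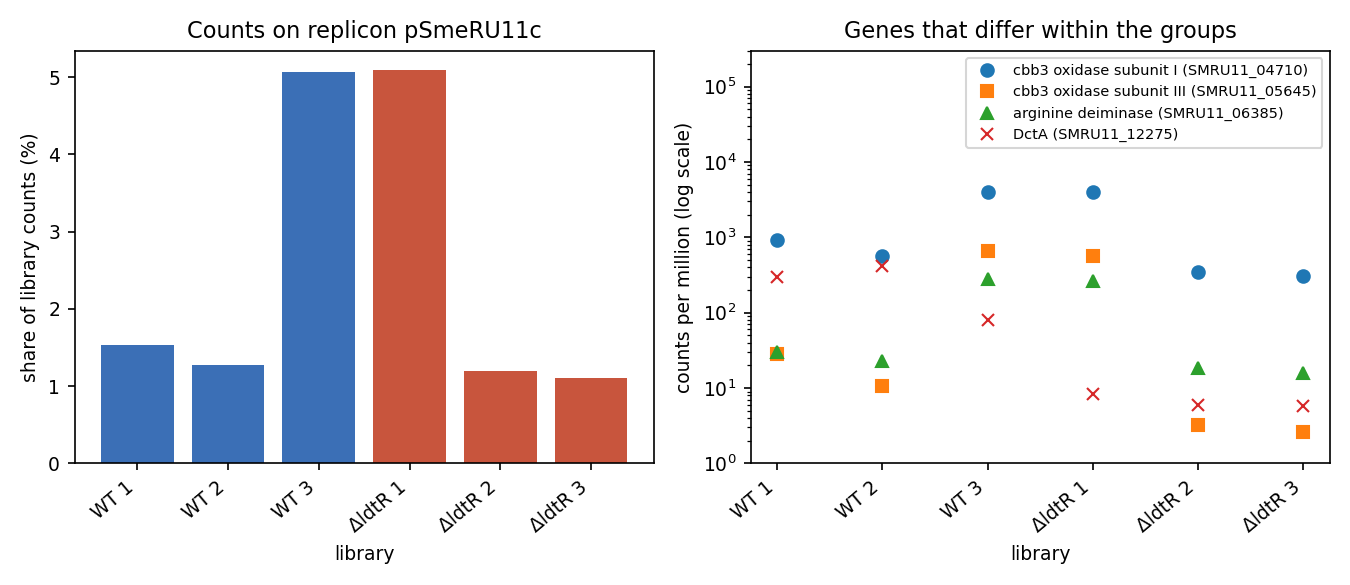
Left, share of each library's counts on plasmid pSmeRU11c in percent, blue for the wild type (WT) and red for ΔldtR; right, CPM on a log scale of the 4 genes in the key, each point 1 library. WT 3 and ΔldtR 1 reach 5.07% and 5.09% where the others stay at or below 1.54%, and the cbb3 oxidase and arginine deiminase points are highest in the same pair, while DctA lies at 79.2 to 417 in the 3 wild-type libraries and 5.77 to 8.29 in the ΔldtR libraries.

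The authors' deposited table gave 155 higher and 86 lower genes at an adjusted p under 0.05. It shared 81 of the 82 calls made here, all 81 with the same sign, and 160 of its calls were not called by edgeR. The log2 ratios correlated across tested genes with r = 0.906, where genes are not independent replicates and both values come from the same libraries. In the authors' deposited table the log2 ratio was −3.80 for ldtR, and −0.23 for motA with an adjusted p of 0.587. For each of the 10 largest falls its ratio was smaller in size than in the DESeq2 fit made here. The transglutaminase gene had −3.99 against −5.58 and the GGDEF gene −2.35 against −3.25. How the authors computed the ratio is not given in the sources used here, so the 2 measures may be unlike. It had motB (−0.53, adjusted p = 0.00292), fliI (−0.41, 0.0243) and visN (−0.38, 0.032) as lower. In it motC, fliN, fliK, rem, fliE, fliQ, flhA and the flagellins were not under 0.05. The shared count followed the edgeR calls when a library was left out, with 16 without wild type 1, 20 without wild type 2, 39 without wild type 3, 173 without ΔldtR 1, 40 without ΔldtR 2 and 19 without ΔldtR 3.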

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

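The fits on 4 libraries and with the share of counts on pSmeRU11c as a covariate were chosen only after the result was seen. The count of 82 called genes stayed within 1.5 times under relative log expression factors (82), upper-quartile factors (89), no filter (82), the stricter filter (81), without the 10 most abundant genes (82) and with the likelihood ratio test (104, 65 higher and 39 lower, 66 of them among the 82). They became 54 (26 higher, 28 lower) with library totals only, 224 with DESeq2, 678 in the 4 libraries (432 higher, 246 lower) and 247 with the covariate, and 16 (without wild type 1) to 431 (without ΔldtR 1, 299 higher and 132 lower) when 1 library was left out, where 15 of the 82 were called in every such fit. The 46 genes of at least 2-fold became 148 in the 4 libraries (83 higher, 65 lower), 11 when tested against a 2-fold bound, and 16 (without wild type 1) to 97 (without ΔldtR 1, 60 higher and 37 lower) with 1 library left out, with 20 without wild type 2 and 18 without ΔldtR 3. The 4 lists became 0 with an estimated correlation and 4 to 7 with 1 library left out. By fry none of these 4 was called (adjusted p 0.148 to 0.552), and its 1 call was the heat shock list as higher (0.0266). The adjusted p for lower calls on pSymA was 0.187 with calls at an adjusted p under 0.01, and 2.91e-09 to 0.187 with 1 library left out, losing the call without wild type 1 (0.172), wild type 2 (0.117) and ΔldtR 3 (0.187). The overlap of 81 with the authors' deposited table became 36 with at least 2-fold in both, 194 with DESeq2 calls, and 16 (without wild type 1) to 173 (without ΔldtR 1). The 2-fold bound may fall on unlike measures there, as the authors' log2 ratios were smaller in size for the largest falls. The replicate number as a block gave 15 genes (1 higher, 14 lower), 15 of at least 2-fold, an adjusted p of 0.172 for pSymA and an overlap of 15. The main difference within the strains did not follow the replicate numbers: deviations of same-numbered libraries correlated at −0.48, 0.41 and −0.52, those of wild type 3 and ΔldtR 1 at 0.65. Deviations were taken from each strain's mean, which ties these correlations together, so they cannot exclude a weaker pairing by number. The 43 named genes were followed only under part of the alternatives. These were DESeq2, relative log expression factors, library totals, the replicate block, each library left out, the 4 libraries and the covariate. No called one changed sign in any of these. The log2 fold change of SMRU11_37890, not called, ran from −0.158 (without wild type 2) to 0.0375 (without wild type 3) with 1 library left out, and was positive also without ΔldtR 2 (0.0193) and in the 4 libraries (0.0229). That of flaD, not called, ran from −0.0364 (without wild type 3) to 0.0976 (without wild type 1), and was negative also without ΔldtR 2 (−0.0356). Except where fewer samples or a stricter test explains it, the cause was not tested. Depth and spread limit small changes: on simulated counts, with genes drawn independently, 10% of 1.5-fold and 54% of 2-fold changes were recovered.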

Other observations

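The tests on swapped labels, plasmid copies, the cbb3 oxidase genes, the flagellar genes and the copies of the phage region were chosen only after the result was seen; the others were fixed before their results were seen.

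Further called genes of carbon metabolism were singled out after their values were seen. Beside the run of citric acid cycle genes, phosphoenolpyruvate carboxykinase (SMRU11_24910), the enzyme that opens gluconeogenesis from organic acids, fell by 1.35 on the log2 scale (edgeR adjusted p = 0.0483) and fructose-bisphosphate aldolase (SMRU11_27835) by 1.02 (0.0303). Glucose-6-phosphate dehydrogenase (SMRU11_21140) rose by 0.99 (0.0324) and glucokinase (SMRU11_24275) by 0.62 (0.0324), both enzymes of glucose use. These 4 genes were not called without wild type 1, 2 or 3 or ΔldtR 3 (highest adjusted p = 0.284), and glucokinase also not without ΔldtR 2 (0.057). The gene of DctA (SMRU11_12275), which takes up C4-dicarboxylates such as succinate, had 297, 417 and 79.2 CPM in the wild-type libraries and 8.29, 6.04 and 5.77 CPM in the ΔldtR libraries, and missed the threshold (log2 fold change −5.30, adjusted p = 0.0743). An α-galactoside-binding gene (SMRU11_12060) differed within the mutant, with 59.1, 2708 and 5727 CPM in ΔldtR 1, 2 and 3 against 108, 69.5 and 293 CPM in the wild type (4.18, adjusted p = 0.433). Of the genes nearly silent in the mutant, transglutaminase gene SMRU11_36780 kept 2.1% of its wild-type counts (exact interval 1.4% to 3.04%), SMRU11_27440 kept 4.38% and SMRU11_17900 kept 4.59%, beside 5.19% for the deleted gene itself.

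A stretch of 50 neighbouring chromosomal genes with phage annotations, SMRU11_21740 to SMRU11_21985, stood out by its higher values in ΔldtR; its bounds were set after the values were seen. It held 11 of the 23 higher calls on the chromosome, among them genes of a capsid protein (SMRU11_21840, log2 fold change 0.75), a head decoration protein (SMRU11_21845, 0.82) and a phage tail protein (SMRU11_21815, 1.02). A positive value was found for 49 of the 50 genes, with a median of 0.67, and in 40 every ΔldtR library lay above every wild type library, where chance gives 5% and all tested genes gave 778 of 7493. As the bounds were chosen for the pattern, these counts describe the stretch and do not test it. The 40 flanking genes had a median of 0.03 and 1 call. Of the 11 calls, 0 were left without wild type 1, 0 without wild type 2, 1 without wild type 3, 3 without ΔldtR 2 and 0 without ΔldtR 3, while the median of these 11 stayed between 0.75 and 0.89.

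Wild type 3 and ΔldtR 1 resembled each other more than their own strains. Swapped strain labels are argued against by ldtR itself, which in wild type 3 stood at 1.12 times the mean of wild type 1 and 2. More copies of plasmid pSmeRU11c would raise its genes together if transcripts followed copies, but 69.9% of its 146 genes were less than 2-fold higher in wild type 3. Less oxygen in these samples was tested on the 12 genes matched to the nitrogen fixation and microaerobic list. Of these 41.7% were above all 4 other libraries in both, below the 50% set beforehand. The 95% interval (15.2% to 72.3%, genes taken as independent, and its use decided after the value was seen) includes 50%. Only 1 of the list's 68 symbols was found as a gene name, and the 12 were nif, fixA and fixJ genes. They held no cbb3 oxidase gene, so the test did not cover that part of the list, and less oxygen stays open. Among all 14 tested genes annotated as cbb3 oxidase the share was 64.3%, or 9 genes. SMRU11_05645 stood at 664 and 565 CPM in the pair against 2.6 to 28.2 in the others. SMRU11_06905, not among the 9, stood at 144.5 and 143.2 CPM against 139.8 to 192.3. This share decides nothing, since the class was chosen after values were seen to be high in this pair, and many of the genes are neighbours. A difference in growth stage or handling was not tested.

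The flagellar genes were lower in ΔldtR by a small amount, with a median relative to the mean of the 6 libraries of 0.33, 0.13 and −0.03 in wild type 1, 2 and 3 and −0.19, −0.13 and −0.14 in ΔldtR. The difference shared by wild type 3 and ΔldtR 1 stays open: without them the median over the 41 genes was −0.37, but the pair holds 1 library of each strain, and the 95% t interval between the library medians of the strains (−0.789 to 0.0641) includes 0. Wild type 1 alone, the library with the highest levels, stays open as well, with a median of −0.223 without it and an interval of −0.401 to −0.00295 that ends close to 0. The highest adjusted p of the 3 lists in these fits was 0.00263 and 0.00523 with the preset correlation but 0.677 and 0.723 with an estimated one, and these intervals and estimated fits were added after the medians were seen. Neither a weaker flagellar program without LdtR nor a difference in culture density between the strains was tested as an explanation.

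For the phage-annotated genes, the median without wild type 3 and ΔldtR 1, 0.649, decides nothing about the difference they share, since the bounds were set on all 6 libraries and the pair holds 1 library of each strain. More copies of the DNA within these bounds would lift all the genes alike if transcripts followed copies. In fact 16% of the 50 genes lay more than 2 SE below the region's median, above the bound of 10%. They included the phage repressor gene SMRU11_21935 (log2 fold change 0.05) and, at one end, the integrase gene SMRU11_21985 (0.14). Genes with their own control, or copies of only a part of the stretch, could give this too, so the test does not exclude more copies. For a response to DNA damage, 13 repair genes such as recA and lexA had a median of −0.0146, below the bound of 0.3. The 95% interval (−0.137 to 0.0354) came from resampled genes and does not measure the spread between libraries. These values argue against a rise of the repair genes across the samples, while a response in few cells would not show in them. Whether the loss of LdtR itself releases these genes was not tested.

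The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For the 82 genes 1 of 10 splits, the real one, gave as many, and the highest other split gave 0; for the 46 genes changed at least 2-fold it was again 1 of 10, with 0 as the highest other. For the 4 called lists 7 of 10 splits gave as many, and the highest other gave 7 lists.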
